A study of Homo sapiens with 30 samples.

How the data were processed

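Total RNA from WI-38 cells, an established line of diploid human lung fibroblasts, was measured on 30 Affymetrix HTA 2.0 arrays, which carry probes over the exons and junctions of coding and non-coding transcripts. Per the labels' protocols, the cells were grown in 3% oxygen and 5% carbon dioxide. One course used cells with a doxycycline-inducible RAF oncogene, induced with 100 ng/ml doxycycline. The other followed cells driven to proliferative exhaustion under 21% oxygen. The 21% oxygen is given for every replicative time except T0, and doxycycline for every RAF time except T0. Against replicative T0, time and the step in oxygen therefore cannot be told apart. Against RAF T0, the oncogene, doxycycline itself and time cannot be told apart, since no later RAF group lacks doxycycline. RNA was extracted with a column kit and turned into biotin-labelled targets with the WT PLUS kit, also per the labels' protocols. Each array was placed in its group by its labels alone, which gave 15 groups of 2 arrays: RAF T0, 12 h, 24 h, 48 h, 72 h and 96 h, and replicative T0, 144 h, 264 h, 432 h, 624 h, 792 h, 1008 h, 1368 h and 2112 h. The design text of the series lists fewer replicative hours than the labels do, and the labels were followed. The design text calls the RAF replicates biological; nothing states this for the replicative arrays, whose p-values may then measure only technical spread.

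The values are the authors' deposited processed values for 52329 features (transcript clusters), read as log2 intensities because they run from -1.6 to 14, a range usual for log2 array values. The log base, the summarisation and the normalization are not given in the sources used here. All 30 arrays have a median of 5.5, and the values are rounded to steps of 0.1, so that small differences are coarse and many values are tied. Scanner files were not used here, so that no background call could be made for a dim feature, and the number of arrays limits the precision. The probe table given with the series names 21055 features with exactly 1 gene symbol, 1406 with several and 29868 with none; the named features carry 19912 different symbols. No symbol changed when it was looked up in the RefSeq gene table. Features with several symbols were tested but never named. A gene with several features was represented by the one with the highest mean over the 30 arrays. Among the genes picked by the rule for named genes below, DCN, GPX3, HLA-DRA, IER3 and RPS18 have several features. None of these gave opposite calls at the endpoints, and other list members were not checked for this. No coordinates are given, because no genome was used.

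Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values), with tables joined in data.table (version 1.17.8). All tests were two-sided. P-values were adjusted over the 52329 features with the Benjamini-Hochberg method, and a feature passed the test at an adjusted p under 0.05. The RAF comparisons used a model of the 12 RAF-labelled arrays (6 groups, 6 residual degrees of freedom), the replicative comparisons a model of the 18 replicative-labelled arrays (9 groups, 9 residual degrees of freedom). The difference of the endpoint effects and the comparison of the T0 groups used a model of all 30 arrays (15 residual degrees of freedom). The main comparisons were RAF 96 h against T0, replicative 2112 h against T0, and the difference between these effects. Replicative 2112 h was also compared with 144 h, both under 21% oxygen, to leave out any step between T0 and 144 h. A feature counted as an early change that was reversed when it passed between the earliest time and T0 and passed in the opposite direction between the last time and the next early time (96 h against 24 h, or 2112 h against 264 h). Groups of 2 arrays are too small for a test of single outlying arrays or for a count over other splits of the arrays.

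Before the data were examined, 24 gene lists, the alternatives and the rule for named genes were fixed. The lists cover S-phase and DNA replication, G2 and mitosis, CDK inhibitors and senescence-associated nuclear proteins, cytokines and chemokines of the senescence-associated secretory phenotype (SASP), SASP proteases with inhibitors and binding proteins, AP-1 and related bZIP factors, ERK pathway output and feedback, p53 targets, interferon-stimulated genes, NF-kB regulators and targets, collagen and fibrous matrix, contractile and TGF-beta-responsive genes, the Notch pathway, cholesterol synthesis, hypoxia and HIF targets, NRF2 and antioxidant genes, lysosome and autophagy, amino acid and unfolded protein stress, heat shock chaperones, ribosomal proteins, and markers of fibroblasts, epithelium, endothelium and leukocytes. Of 464 listed members, 409 had a feature named here. Each list was tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 24 lists, and again with the correlation estimated from the data. Beside the counts over all features, the members were adjusted over the list alone. The level of a list in an array is the mean over its members of the value minus that member's mean over the 30 arrays.

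The genes named are, for each main comparison, the 5 largest changes each way among those that passed with both arrays of one group above both arrays of the other, up to 4 members of each list, and a fixed set of senescence, RAF and AP-1 genes. For the difference of effects this separation of the arrays was not asked. Uncharacterised loci, antisense, microRNA, snoRNA, small nuclear RNA and Y RNA names and pseudogenes were left out of the largest changes. For the T0 comparison, the comparison of 2112 h with 144 h and the reversed early changes, the 5 largest each way were taken. Of the RAF kinase genes, only ARAF had a feature named here. Values of these genes at other times come from the same models.

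The steps were tested on simulated data with 52329 features, in which 200 drawn at random were changed by known amounts. All members of the mitosis list were raised by 0.5 as well. Features changed by 0.5, 1 and 2 log2 units were recovered in 40.3%, 76.1% and 98.5% of cases for RAF 96 h against T0, in 56.7%, 98.5% and 100% for replicative 2112 h against T0, and in 34.3%, 91% and 98.5% for the difference of effects. False calls made up 7.5%, 7% and 3.2% of the calls.

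Alternatives fixed beforehand were quantile normalization, median centring, leaving out the dimmest 25% of features, eBayes with trend and robust settings, array weights, other samples in the model, the replicate number as a block, leaving out each array in turn, a minimum of 2-fold, an adjusted p under 0.01, only features with 1 symbol, the mean of a gene's features, and the estimated correlation for lists. Undoing the rounding at random (a uniform draw of up to 0.05 either way) and leaving out the arrays labelled replicative 144 h, 264 h and 432 h were added after the data were seen.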

Results

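The series followed WI-38 fibroblasts into senescence, a lasting exit from the cell cycle with a secretory phenotype, along 2 courses. In the RAF course, an inducible RAF oncogene was switched on with doxycycline, and RNA was taken at T0, 12 h, 24 h, 48 h, 72 h and 96 h. In the replicative course, cells were grown to exhaustion under 21% oxygen. They were sampled at T0, 144 h, 264 h, 432 h, 624 h, 792 h, 1008 h, 1368 h and 2112 h. The T0 arrays come from before the 21% oxygen, so every comparison with replicative T0 also holds this step. Each labelled group held 2 arrays, 30 arrays in all, with values for 52329 features on a log2 scale. Partner arrays correlated over features at 0.9921 to 0.9969 and shared 27.7% to 38.4% of their rounded values, so that none was a copy of its partner. For 28 of the 30 arrays the partner was the most highly correlated array.

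In the RAF course, the mitotic genes, which a senescent arrest would lower, stood lowest in the arrays labelled RAF T0 (list level -1.38 ± 0.09, SD, n = 2) and higher in the arrays of every later RAF label, reaching 1.42 ± 0.08 at 12 h and 1.08 ± 0.08 at 96 h. ERK pathway output, the feedback genes that RAF signalling raises, lay between -0.43 and -0.28 in all RAF-labelled groups. It passed upwards against RAF T0 at 48 h, 72 h and 96 h with camera at the preset correlation only. In the replicative course the mitotic genes were lower than at T0: all 27 members fell at 144 h to 432 h and at 792 h to 1368 h, 18 at 624 h and 19 at 2112 h. All 27 were higher at 2112 h than at 144 h. ERK output lay at 0.37 ± 0.05 in the arrays labelled replicative T0 and between 0.61 and 0.84 in those labelled 792 h to 2112 h. In those labelled 624 h its mean change against T0 was -0.765, so that it lay below 0 there. On component 1 of a principal component analysis, which held 64.2% of the variance, the 12 arrays labelled replicative T0, 624 h, 792 h, 1008 h, 1368 h and 2112 h lay above 0, from 25.24 upwards. The other 18, all 12 RAF-labelled arrays and those labelled replicative 144 h, 264 h and 432 h, lay at -37.23 or below. Groups are therefore named throughout as arrays labelled with a time, and each direction below is a direction between labels.

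**Figure D1:**
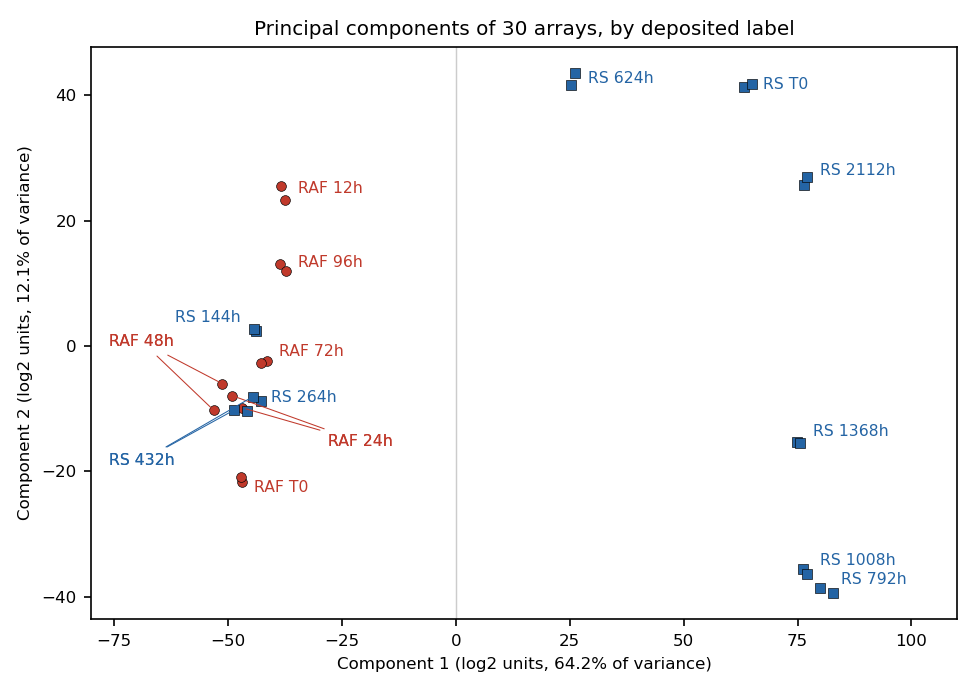
Principal components 1 and 2 of the 30 arrays (both axes in log2 units, with the percent of variance held), where each point is 1 array, red for RAF labels and blue for replicative labels (written RS). The 12 arrays labelled replicative T0 and 624 h to 2112 h lie above 0 on component 1, and the other 18 lie below.

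**Figure D2:**
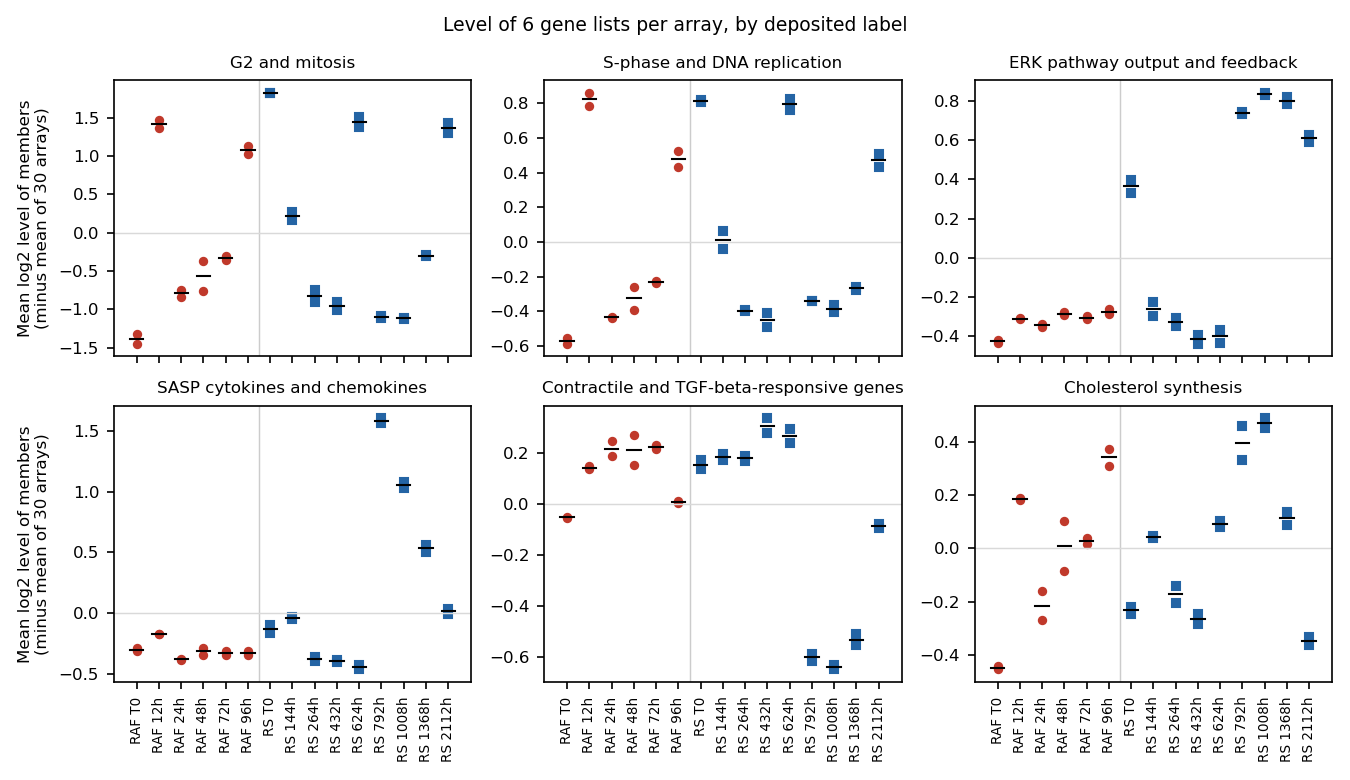
Level of 6 gene lists in each array (mean log2 value of the members minus their mean over the 30 arrays, vertical axis) by label (horizontal axis), with 1 point per array and a bar at the mean of the 2 arrays. ERK pathway output lies below 0 in every RAF-labelled array and above 0 in those labelled replicative T0 and 792 h to 2112 h. Its mean at replicative 624 h lies below 0.

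Genes of cell division stood far higher in the arrays labelled RAF 96 h than in those labelled RAF T0, the comparison meant to show the state reached under the oncogene. ANLN (feature TC07000235.hg.1), an actin-binding protein of the cleavage furrow, was higher by 4.10 log2 units (SE 0.16, adjusted p 1.9e-05). TOP2A, which untangles DNA before division, was higher by 3.95 (SE 0.18), the spindle protein DLGAP5 by 3.75 (SE 0.19), the proliferation marker MKI67 by 3.40 (SE 0.13) and the spindle pole protein ASPM by 3.15 (SE 0.16). All 27 measured members of the G2 and mitosis list rose (27 adjusted over the list alone), with a median of 2.35, a list adjusted p of 4.22e-37 and an adjusted p of 0.0771 with an estimated correlation. These directions run from the labelled T0 to the labelled 96 h, in a course where the mitotic genes stood lowest at T0.

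The DNA replication genes moved with them: 26 of 29 members rose (28 adjusted over the list alone), among them RRM2 by 2.15 (SE 0.11) and CDC6 by 2.05 (SE 0.15), with a median of 0.85. Cholesterol synthesis rose in 13 of 14 members (13 adjusted over the list alone, median 0.68), including HMGCS1 by 1.35 (SE 0.07) and INSIG1 by 1.35 (SE 0.11). Ribosomal proteins rose in 13 of 14 (13 adjusted over the list alone) by a narrow margin, with a median of 0.35. Collagen and matrix genes split, with 10 members up and 2 down of 20 (10 and 2 adjusted over the list alone). The matrix protein POSTN rose by 2.15 (SE 0.16), while the small proteoglycan LUM fell by 1.40 (SE 0.10). LMNB1, the nuclear lamina protein that is lost in senescent cells, rose by 2.20 (SE 0.14), and the list of CDK inhibitors and senescence-associated nuclear proteins held 5 rises and 1 fall among 11 (5 and 2 adjusted over the list alone).

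The members that fell included the p53-induced cell cycle inhibitor CDKN1A, by 0.40 (SE 0.04), and TP53INP1, another p53 target, by 0.95 (SE 0.10). Of 22 p53 targets 11 fell and 2 rose (11 and 3 adjusted over the list alone). Lysosome and autophagy genes fell in 9 of 19 and the other 10 did not pass (12 falls adjusted over the list alone), the collagen-degrading protease CTSK by 0.75 (SE 0.09). NRF2 and antioxidant genes fell in 8 and rose in 3 of 20 (9 and 3 adjusted over the list alone), with AKR1C2 lower by 1.40 (SE 0.08) and the quinone reductase NQO1 higher by 0.60 (SE 0.08). Outside the lists, the steepest falls were in ALKAL1, a receptor tyrosine kinase ligand, by 2.90 (SE 0.18), in FGL2 by 2.80 (SE 0.16), in the cystatins CST1 by 2.75 (SE 0.24) and CST4 by 2.55 (SE 0.15), and in the olfactory receptor gene OR5B12 by 2.65 (SE 0.23).

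Of the lists that the oncogene should reach, ERK output passed upwards between these labels. The AP-1 and SASP lists held members that went each way and did not pass. ERK output rose in 8 and fell in 1 of 20 members (9 and 2 adjusted over the list alone), with a median of 0.10, a list adjusted p of 0.00298 and an adjusted p of 0.0771 with an estimated correlation. The feedback inhibitor SPRY4 rose by 0.55 (SE 0.06) and the ERK phosphatase DUSP6 by 0.30 (SE 0.05). Among 17 AP-1 and related factors 4 rose and 2 fell (5 and 3 adjusted over the list alone), and the list as a whole did not pass (adjusted p 0.456). FOS rose by 0.85 (SE 0.12), FOSL1 by 0.65 (SE 0.08) and FOSB by 0.60 (SE 0.13), while JUN fell by 0.35 (SE 0.07) and FOSL2 by 0.30 (SE 0.05). JUNB (0.10, adjusted p 0.295), ATF3 (-0.10, adjusted p 0.584) and ARAF (0.00, adjusted p 1) did not pass. In the SASP cytokine list 2 members rose and 1 fell of 19 (2 and 1 adjusted over the list alone; list adjusted p 0.725). IL1A (0.05), IL1B (0.20), IL6 (0.20) and CXCL8 (0.05) did not pass, nor did CDKN2A (-0.15) or CDKN2B (0.00). SASP proteases gave 6 rises and 8 falls of 23 (7 and 10 adjusted over the list alone; list adjusted p 0.521), with the collagenase MMP1 up by 1.60 (SE 0.18) and IGFBP3 down by 1.40 (SE 0.09).

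Most other lists did not pass between the arrays labelled RAF 96 h and T0. Interferon-stimulated genes held 1 rise and 6 falls of 22 (2 and 7 adjusted over the list alone; list adjusted p 0.0696), hypoxia targets 3 and 9 of 25 (4 and 10; list adjusted p 0.0533), and NF-kB genes 3 and 2 of 17 (4 and 3; list adjusted p 0.712). Contractile genes held 8 rises and 5 falls of 21 (8 and 5; list adjusted p 0.143). Amino acid and unfolded protein stress genes held 6 and 5 of 15 (6 and 6; list adjusted p 0.769), the Notch pathway 1 rise of 13 (1; list adjusted p 0.725), and heat shock chaperones 2 rises of 9 (2; list adjusted p 0.521). Fibroblast markers gave 4 rises and 4 falls of 11 (4 and 5; list adjusted p 0.615), epithelial markers 2 rises of 10 (2; list adjusted p 0.307), and leukocyte markers 1 fall of 8 (1; list adjusted p 0.617); among 9 endothelial markers no member passed limma's test (3 lower at an unadjusted p under 0.05), at a list adjusted p of 0.615.

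Over all features, 4173 rose and 4036 fell between the arrays labelled RAF T0 and RAF 96 h, 8209 of 52329. At least 2-fold, 314 rose and 305 fell. With camera at the preset correlation, 7 lists passed upwards and 3 downwards, and none held with an estimated correlation: the adjusted p was 0.0771 with an estimated correlation for mitosis, ERK output and ribosomal proteins, 0.0509 for DNA replication and for lysosome genes, and 0.114 for cholesterol synthesis. For p53 targets it was an adjusted p of 0.188 with an estimated correlation, for collagen 0.348 and for NRF2 genes 0.432. For the list of CDK inhibitors and senescence-associated nuclear proteins it was 0.129. The count fell by more than 1.5 times without RAF T0 replicate 1 (5318 features) or without RAF T0 replicate 2 (4989).

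**Figure D3:**
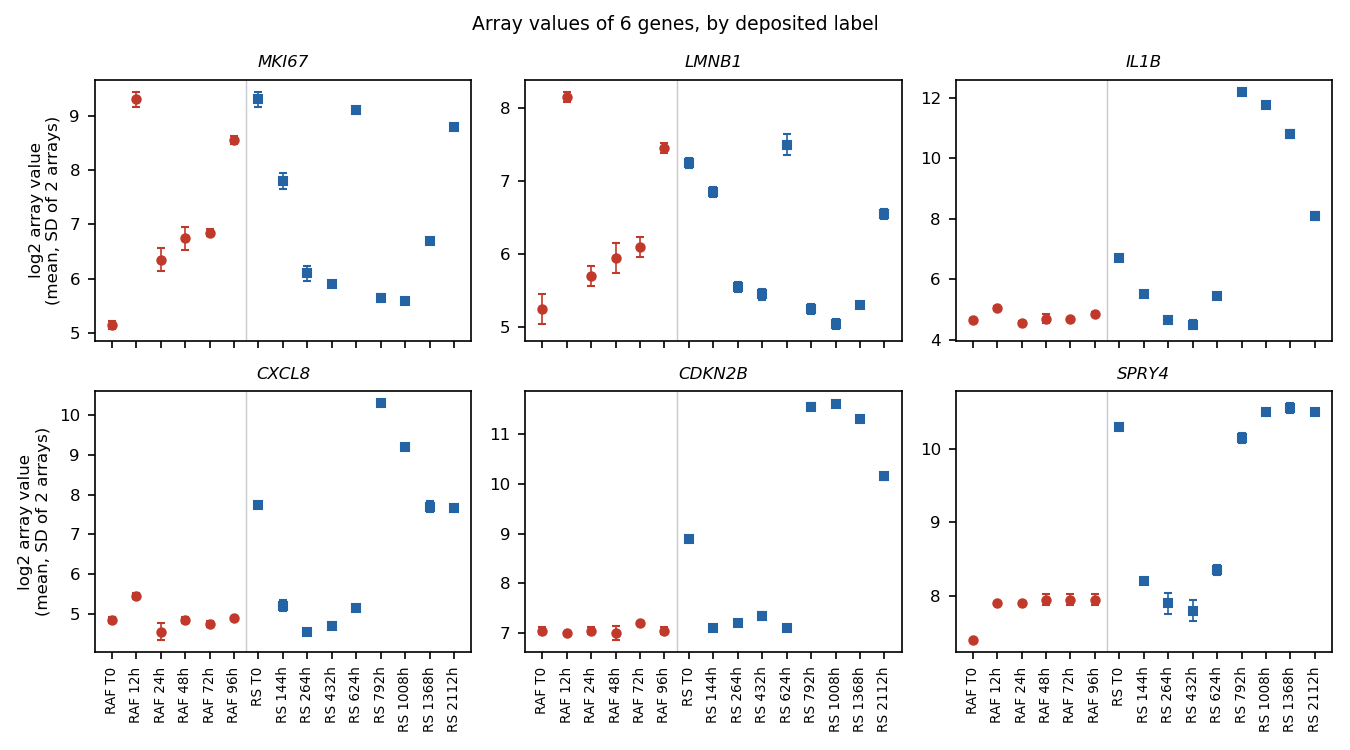
Array values (log2, vertical axes) of MKI67, LMNB1, IL1B, CXCL8, CDKN2B and SPRY4 by label, with points at the mean of 2 arrays and bars of 1 SD. MKI67 is lowest in the arrays labelled RAF T0, at 5.15, and IL1B is highest in those labelled replicative 792 h, at 12.20.

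The mitosis list passed upwards against T0 at every RAF label with the preset correlation, with a number of members past the test that varied between labels. All 27 mitotic members stood higher in the arrays labelled 12 h than in those labelled T0 (27 adjusted over the list alone, median 2.80), against 9 at 24 h (20 adjusted over the list alone, median 0.55), 18 at 48 h (23, median 0.75) and 24 at 72 h (27, median 1.0). With an estimated correlation the adjusted p was 0.05, 0.362, 0.174 and 0.138 at these labels, and the call was lost at each. Replication was held at 12 h with an estimated correlation, with 27 rises and 1 fall of 29 (28 and 1 adjusted over the list alone, adjusted p 0.0316). So were NF-kB genes, with 10 rises and 1 fall of 17 (13 and 2, adjusted p 0.0263), and lysosome genes, with 13 falls of 19 (14, adjusted p 0.0263). ERK output passed upwards at 48 h in 7 members with 2 down (8 and 3 adjusted over the list alone) and at 72 h in 6 with 2 down (9 and 3), at list adjusted p of 0.00345 and 0.00884 and an adjusted p of 0.116 and 0.138 with an estimated correlation. MKI67 lay at 5.15 ± 0.07 in the arrays labelled T0, 9.30 ± 0.14 at 12 h, 6.35 ± 0.21 at 24 h, 6.75 ± 0.21 at 48 h, 6.85 ± 0.07 at 72 h and 8.55 ± 0.07 at 96 h (SD, n = 2 each). Features that passed against T0 numbered 5076 up and 5089 down at 12 h, 1382 and 1707 at 24 h, 2071 and 2274 at 48 h, and 2270 and 2338 at 72 h; 10237 features changed at any RAF time in limma's joint test.

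Several of these counts were lower by more than 1.5 times when 1 array was left out, which also leaves an arm of 1 array. Leaving out any 1 of the 4 arrays compared took the 24 h count from 3089 to between 1195 and 1378, and the 72 h count from 4608 to between 1603 and 2565. The 48 h count of 4345 became 2236 without RAF T0 replicate 1, 2348 without RAF T0 replicate 2 and 2330 without RAF 48 h replicate 2.

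Some RAF features passed at 12 h against T0 and stepped the other way between 24 h and 96 h, which need not bring them back to T0. The proteoglycan BGN was higher in the arrays labelled 12 h than at T0 by 1.05 (SE 0.06) and lower at 96 h than at 24 h by 0.25 (SE 0.06). At 96 h it still stood above T0 by 0.70 (adjusted p 0.000176). TNFSF4, a ligand of the tumour necrosis factor family, rose by 0.90 (SE 0.06) and then fell by 0.60 (SE 0.06), and MN1, CCN4 and ADH1B followed the same order. The protease inhibitor TFPI2 fell by 1.30 (SE 0.06) and then rose by 0.30 (SE 0.06), and the amino acid transporter SLC6A15 fell by 1.30 (SE 0.14) and rose by 0.75 (SE 0.14), as did INA, ITGA6 and NT5E. TFPI2 and SLC6A15 remained below T0 at 96 h, by 0.45 and 0.55. In all, 122 features rose first and 132 fell first. Single omissions gave between 118 and 190 features, and 5 of the 8 arrays moved the total of 254 by more than 1.5 times.

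In the replicative course, the SASP protease list passed upwards between the arrays labelled replicative T0 and 2112 h, and 3 SASP cytokines and the CDK inhibitor CDKN2B rose. The SASP cytokine list did not pass. Nor did the list of CDK inhibitors and senescence-associated nuclear proteins, whose members went each way. ACP3 (feature TC03000714.hg.1), an acid phosphatase, rose by 2.10 log2 units (SE 0.06, adjusted p 1.25e-08). Other rises were SLC6A15 by 1.90 (SE 0.06), the synaptic adhesion protein SLITRK6 by 1.5 (SE 0.08), the cystatin CST4 by 1.45 (SE 0.19) and the cytokine TNFSF15 by 1.45 (SE 0.09). The inflammatory cytokines IL1B and IL1A rose by 1.40 (SE 0.09) and 1.30 (SE 0.07), and CDKN2B by 1.25 (SE 0.05). Among the falls were ANKRD1, a stretch-responsive nuclear protein, by 1.20 (SE 0.11), the vasoconstrictor peptide EDN1 by 0.85 (SE 0.12), and LPPR4, NTN4 and TGFB2 by 0.80 each (SE 0.07, 0.07 and 0.10). These are directions between labels, and ERK output was already above its mean over all arrays in those labelled T0.

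SASP proteases and binding proteins rose in 7 of 23 members and the other 16 did not pass (12 rises adjusted over the list alone, median 0.20), among them the growth factor EREG by 1.30 (SE 0.13), the stromelysin MMP3 by 0.90 (SE 0.14) and MMP10 by 0.60 (SE 0.10). ERK output rose in 6 of 20 (12 up and 1 down adjusted over the list alone, median 0.25), with IER3 up by 0.60 (SE 0.07), SPRY2 by 0.50 (SE 0.08) and DUSP6 by 0.45 (SE 0.06), while SPRY4 (0.20, adjusted p 0.258) did not pass. Lysosome genes rose in 4 of 19 (5 adjusted over the list alone, median 0.10). Mitotic genes fell in 19 of 27 (26 adjusted over the list alone, median -0.50) and replication genes in 16 of 29 (26, median -0.35), with MKI67 lower by 0.50 (SE 0.08), RRM2 by 0.50 (SE 0.07) and LMNB1 by 0.70 (SE 0.08). Contractile and TGF-beta-responsive genes fell in 10 and rose in 1 of 21 (13 and 2 adjusted over the list alone, median -0.20), including the matricellular proteins CCN1 by 0.65 (SE 0.07) and CCN2 by 0.55 (SE 0.07). Cholesterol synthesis held 1 rise and 3 falls of 14 (1 and 5 adjusted over the list alone), with an adjusted p of 0.511 with an estimated correlation; MSMO1 fell by 0.35 (SE 0.07) and INSIG1 rose by 0.35 (SE 0.08).

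AP-1 and related factors gave 1 fall among 17 (2 up and 2 down adjusted over the list alone; list adjusted p 0.41): JDP2 fell by 0.25 (SE 0.06), and FOS (0.55, adjusted p 0.431), JUNB (0.35, adjusted p 0.116), FOSL1 (-0.25, adjusted p 0.171), FOSL2 (-0.10), JUN (0.00) and ATF3 (-0.05) did not pass. In the SASP cytokine list IL1A, IL1B and LIF (0.60, SE 0.10) rose and the other 16 did not pass (3 adjusted over the list alone; list adjusted p 0.18), including IL6 (-0.05) and CXCL8 (-0.10). CDKN1A (0.10), CDKN2A (0.20), MMP1 (0.40) and ARAF (0.05) did not pass. The list of CDK inhibitors and senescence-associated nuclear proteins held 1 rise and 3 falls of 11. Adjusted over the list alone these were 2 and 3, at a list adjusted p of 0.41. The rise was in CDKN2B, and the falls were in the nuclear proteins LMNB1, HMGB2 and EZH2, not in CDK inhibitors. NF-kB genes gave 1 rise of 17 (4 up and 1 down adjusted over the list alone; list adjusted p 0.072), hypoxia targets 2 rises and 1 fall of 25 (2 and 2; 0.105), stress genes 2 falls of 15 (2 up and 6 down; 0.0897), p53 targets 2 and 1 of 22 (2 and 1; 0.891), and interferon-stimulated genes 1 rise of 22 (1; 0.537). Collagen genes gave 1 rise and 2 falls of 20 (2 and 4; 0.6), NRF2 genes 1 and 1 of 20 (5 and 2; 0.365), and fibroblast markers 2 and 1 of 11 (2 and 1; 0.6). No member of the Notch, heat shock, ribosomal, epithelial, endothelial or leukocyte lists passed limma's test, with list adjusted p of 0.6, 0.624, 0.928, 0.891, 0.41 and 0.891. At an unadjusted p under 0.05, 2 Notch, 2 heat shock, 2 endothelial and 1 leukocyte members were higher, 1 epithelial and 2 endothelial members lower, and 0 ribosomal either way.

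Over all features 700 rose and 764 fell between the arrays labelled replicative T0 and 2112 h, and at least 2-fold 39 rose and 3 fell. With camera 3 lists passed upwards and 4 downwards. All of them except cholesterol synthesis held with an estimated correlation, at adjusted p of 0.00261 for SASP proteases, 0.0165 for replication, 0.0168 for ERK output, 0.019 for mitosis and contractile genes, and 0.0338 for lysosome genes. The count of 1464 fell whichever of the 4 arrays was left out, which leaves an arm of 1 array: it was 513 without replicative T0 replicate 1, 523 without replicative T0 replicate 2, 377 without 2112 h replicate 1 and 512 without 2112 h replicate 2.

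Against replicative T0, the arrays labelled 792 h, 1008 h and 1368 h had higher IL1A and IL1B, higher CDKN2B, CDKN2A and CDKN1A, and lower division genes. IL1B was higher by 5.50, 5.05 and 4.10 (SE 0.09 each), IL1A by 4.85, 4.6 and 3.65 (SE 0.07), CDKN2B by 2.65, 2.70 and 2.40 (SE 0.05) and MMP3 by 3.15, 2.15 and 1.45 (SE 0.14). CDKN2A, the p16 and p14 locus, rose by 1.05, 0.90 and 0.80 (SE 0.06) and CDKN1A by 0.90, 0.70 and 0.40 (SE 0.05). At each label the list of CDK inhibitors and senescence-associated nuclear proteins held these 3 rises and 5 falls of 11. The counts were the same adjusted over the list alone (3 and 5). With members going each way, the list as a whole did not pass (list adjusted p 0.346, 0.237 and 0.211). MKI67 was lower by 3.65, 3.70 and 2.60 (SE 0.08). At these labels FOSL1 fell by 1.75, 1.60 and 1.30 (SE 0.08) while JUNB rose by 1.40, 1.25 and 0.80 (SE 0.10).

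SASP cytokines rose in 15 of 19 members at 792 h, 12 at 1008 h and 6 at 1368 h (15, 12 and 7 adjusted over the list alone), with medians of 1.35, 0.50 and 0.10, and the call of the list at 1368 h had an adjusted p of 0.0561 with an estimated correlation. All 27 mitotic members fell at each of the 3 labels (27 adjusted over the list alone), with medians of -3.20, -3.10 and -2.25. Contractile genes fell in 17, 16 and 16 of 21 members (17, 16 and 16 adjusted over the list alone), among them TAGLN by 1.85 (SE 0.06) and CNN1 by 1.95 (SE 0.06) at 792 h. NF-kB genes rose in 15, 14 and 8 of 17 (16, 15 and 9 adjusted over the list alone), with ICAM1, an adhesion molecule, up by 2.90 (SE 0.09) at 792 h. The NF-kB call at 1368 h had an adjusted p of 0.099 with an estimated correlation. p53 targets rose in 18, 16 and 12 of 22 (18, 17 and 14 adjusted over the list alone), and the p53-responsive cytokine GDF15 by 2.65 (SE 0.06) at 792 h. Counts were 6853 up and 6122 down at 792 h, 6105 and 5928 at 1008 h, and 4575 and 4399 at 1368 h. All these arrays lay above 0 on component 1, as did the arrays labelled T0.

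In the arrays labelled 624 h, ERK output was lower than in those labelled replicative T0, and secretory genes went both ways. ERK output fell in 17 of 20 members and rose in 1 (18 and 1 adjusted over the list alone, median -0.60, adjusted p 0.00319 with an estimated correlation), SPRY4 by 1.95 (SE 0.08) and DUSP6 by 1.55 (SE 0.06). IL1A was lower by 1.90 (SE 0.07), CXCL8 by 2.60 (SE 0.08) and CDKN2B by 1.80 (SE 0.05). TGFB2 was higher by 1.5 (SE 0.10), CCL2 by 1.45 (SE 0.10) and IL6 by 0.85 (SE 0.12). SASP cytokines fell in 7 of 19 and rose in 2 (7 and 2 adjusted over the list alone, adjusted p 0.124 with an estimated correlation). SASP proteases fell in 12 of 23 and rose in 3 (13 and 4 adjusted over the list alone, adjusted p 0.00728 with an estimated correlation). Mitotic genes fell in 18 of 27 (20 adjusted over the list alone), with a median of -0.35 and an adjusted p of 0.119 with an estimated correlation. In all 3754 features rose and 3488 fell, 7242 in total, with 4217 without replicative T0 replicate 2 and 4035 without 624 h replicate 1.

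Against replicative T0, the arrays labelled 144 h, 264 h and 432 h had lower mitotic genes in all 27 members (27 adjusted over the list alone), with medians of -1.55, -2.75 and -2.85, and lower ERK output in 16, 14 and 15 of 20 (16, 14 and 15 adjusted over the list alone). SPRY4 was lower by 2.10, 2.40 and 2.50 (SE 0.08) and CDKN2B by 1.80, 1.70 and 1.55 (SE 0.05), while ATF3 was higher by 1.80, 1.65 and 1.30 (SE 0.19). The adjusted p with an estimated correlation was 0.13, 0.0954 and 0.0611 for mitosis, and 0.13, 0.113 and 0.0611 for ERK output. Counts were 15774 up and 14965 down at 144 h, 15897 and 13879 at 264 h, and 16320 and 14031 at 432 h. All 3 comparisons cross 0 on component 1, so that the division of the arrays and the label cannot be told apart. In limma's joint test 38841 features changed at any replicative time, and 17766 without the arrays labelled 144 h, 264 h and 432 h.

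Between the arrays labelled replicative 144 h and 2112 h, all 27 mitotic members were higher in those labelled 2112 h (27 adjusted over the list alone, median 1.10, adjusted p 0.185 with an estimated correlation). SLC6A15 rose by 4.0 (SE 0.06), HAS2, a hyaluronan synthase, by 4.30 (SE 0.07), and ESM1, SEMA7A and MMP10 by 4.15, 3.95 and 3.90. FGL2 fell by 5.60 (SE 0.21), CEMIP by 4.20 (SE 0.09), the adhesion molecule VCAM1 by 4.0 (SE 0.11), the chemokine CCL2 by 3.90 (SE 0.10) and the desaturase SCD by 3.30 (SE 0.08). In total 15581 features rose and 16193 fell. Reversed early changes numbered 12706 up first and 11642 down first, led by FGL2, VCAM1, CEMIP, CCL2 and HBD upwards and by HAS2, ESM1, SEMA7A, MMP10 and CD274 downwards. Both counts cross 0 on component 1 as well.

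**Figure D4:**
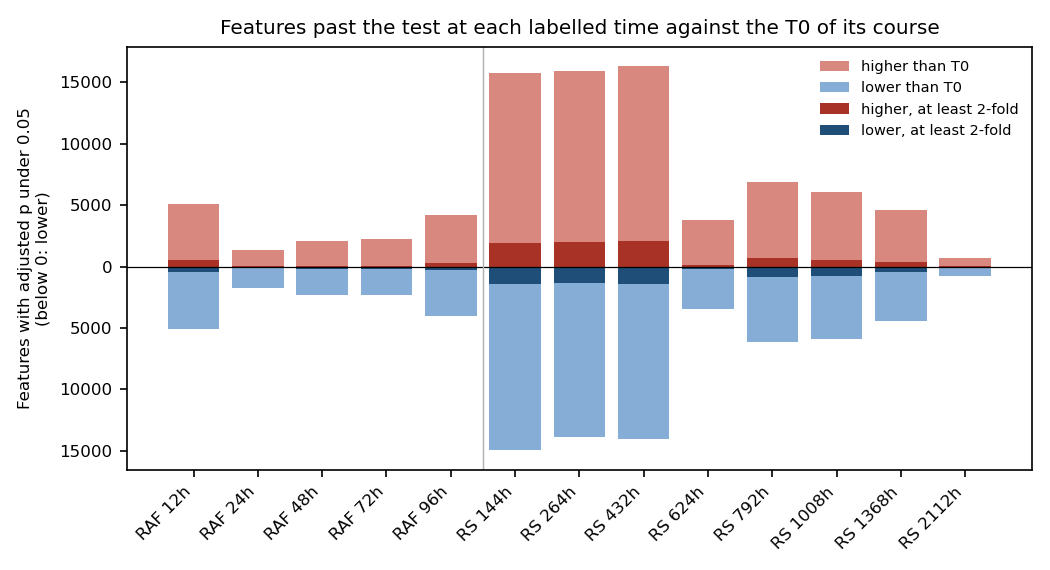
Number of features with an adjusted p under 0.05 at each label against the T0 of its course (horizontal axis: label; vertical axis: features, with those lower than T0 drawn below 0), where the dark part of each bar holds changes of at least 2-fold. The arrays labelled replicative 144 h, 264 h and 432 h have the tallest bars, with 15774, 15897 and 16320 features above T0.

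The endpoint effects of the courses differed in the division genes, which rose between the RAF labels and fell between the replicative labels. The difference (RAF effect minus replicative effect) was 4.55 for ANLN (SE 0.19, adjusted p 2.99e-11), 4.50 for TOP2A (SE 0.20), 4.25 for DLGAP5 (SE 0.21), 3.90 for MKI67 (SE 0.15), 3.65 for ASPM (SE 0.16) and 2.90 for LMNB1 (SE 0.15). It was -4.10 for CST1 (SE 0.29), -4.0 for CST4 (SE 0.26), -2.95 for SLITRK6 (SE 0.22), -2.90 for ALKAL1 (SE 0.21) and -2.80 for VCAM1 (SE 0.25). CDKN2B (-1.25, SE 0.09), IL1A (-1.25, SE 0.13) and IL1B (-1.20, SE 0.12) also differed, and FOSL1 by 0.90 (SE 0.12). FOS, FOSL2, JUN, JUNB and ATF3 did not pass, with differences of 0.30, -0.20, -0.35, -0.25 and -0.05.

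By list, the difference was positive in all 27 mitotic members (27 adjusted over the list alone, median 2.90) and in 27 of 29 replication members (28, median 1.15). It was positive in 12 of 14 cholesterol genes (13 adjusted over the list alone, median 0.75) and 12 of 14 ribosomal proteins (13, median 0.40), and negative in 13 of 19 lysosome genes (14, median -0.35). These 5 held with an estimated correlation, at adjusted p of 0.0015, 0.000705, 0.0104, 0.0202 and 0.000993. A further 7 lists passed only at the preset correlation: the adjusted p was 0.0609 with an estimated correlation for SASP proteases (median -0.40), 0.0903 for contractile genes (median 0.35) and 0.25 for hypoxia targets (median -0.15). For collagen (median 0.30), p53 targets (median -0.15) and NRF2 genes (median -0.12) it was an adjusted p of 0.134 with an estimated correlation. The list of CDK inhibitors and senescence-associated nuclear proteins (median 0.05) had the same adjusted p. The AP-1 list did not differ past the test (adjusted p 0.991), nor did ERK output (adjusted p 0.237). Over all features 3664 differences were positive and 3485 negative.

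Features that changed at both endpoints went both in the same and in opposite directions. The falls shared by both courses numbered 121 (58.9 expected of independent lists, odds ratio 2.29) and the shared rises 105 (55.8 expected, odds ratio 2.06), 226 features together. Features up under the RAF labels and down under the replicative labels numbered 333 (60.9 expected, odds ratio 9.6, Fisher's exact test, adjusted p 5.72e-160), and the converse 149 (54 expected, odds ratio 3.32). The effects correlated across features at a Pearson r of -0.11 and a Spearman rho of -0.07, and features are not independent replicates. The shared total became 91 without replicative T0 replicate 1, 95 without replicative T0 replicate 2, 82 without 2112 h replicate 1 and 84 without 2112 h replicate 2.

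The arrays labelled T0 of the courses were far apart. In those labelled RAF T0, FGL2 was higher by 5.95 (SE 0.20), VCAM1 by 5.65 (SE 0.18), the metalloproteinase ADAMTS19 by 4.55 (SE 0.09), CCL2 by 4.40 (SE 0.10) and HBD by 4.25 (SE 0.16). HAS2 was lower by 5.45 (SE 0.09), ASPM and TOP2A by 4.25 (SE 0.12 and 0.14), the kinetochore motor CENPE by 4.20 (SE 0.10) and MKI67 by 4.15 (SE 0.11). All 27 mitotic members were lower (27 adjusted over the list alone, median -3.20), with an adjusted p of 0.0511 with an estimated correlation. ERK output was lower in 15 and higher in 3 of 20 (15 and 3 adjusted over the list alone, median -0.88), with an adjusted p of 0.0279 with an estimated correlation. In total 16045 features were higher and 14753 lower in the arrays labelled RAF T0; this comparison too crosses 0 on component 1.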

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

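All tests of explanations in this part were chosen after the results they bear on had been seen, and so were their bounds.

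The endpoint effects differed between the labelled courses, by a test of the difference itself, for 7149 features. The median difference (RAF minus replicative, log2) was 1.15 for DNA replication, 2.90 for mitosis, 0.75 for cholesterol synthesis, 0.40 for ribosomal proteins, 0.35 for contractile genes and 0.30 for collagen. For the list of CDK inhibitors and senescence-associated nuclear proteins it was 0.05, although the inhibitors CDKN2B, CDKN1A and CDKN2A differed downwards. It was -0.40 for SASP proteases, -0.35 for lysosome genes, -0.15 for p53 targets and for hypoxia targets, and -0.12 for NRF2 genes. These calls are at the preset correlation. With an estimated correlation only replication, mitosis, cholesterol synthesis, ribosomal proteins and lysosome genes held, and for the other 7 the adjusted p was 0.0609 (SASP proteases), 0.0903 (contractile genes), 0.25 (hypoxia targets) or 0.134 (the rest). Single genes differed by 4.55 (ANLN), 4.50 (TOP2A), 4.25 (DLGAP5), 3.90 (MKI67), 3.65 (ASPM), 2.90 (LMNB1), 1.20 (MMP1), 0.90 (FOSL1) and 0.35 (SPRY4). In the other direction they differed by -4.10 (CST1), -4.0 (CST4), -2.95 (SLITRK6), -2.90 (ALKAL1), -2.80 (VCAM1), -1.25 (CDKN2B and IL1A), -1.20 (IL1B), -0.75 (MMP3), -0.50 (CDKN1A) and -0.35 (CDKN2A).

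Against RAF T0 the mitosis list passed upwards at every RAF label with the preset correlation, with 9 (24 h) to 27 of its 27 members past the test, and at none with an estimated correlation. Against an arrest reached by 96 h in arrays that carry their true labels stand these directions. The replication genes had a median rise of 0.85 and 26 of 29 members up (adjusted p 0.0509 with an estimated correlation). They moved with the mitotic genes, so they restate the pattern and are not separate evidence. Against the swap of a single array labelled RAF T0 with one of another RAF label stands that the mitosis levels of the 2 arrays labelled RAF T0 differ by 0.13, where the nearest other label lies 0.59 away (SD of a difference within pairs 0.19). Titles out of step with the value columns, with partner arrays moved together, cannot be told apart from other causes: the low ERK output (highest median rise at any RAF label 0.15) helped to raise this question and so decides nothing. An induction that failed, in cells at rest at T0, was not tested and stays open.

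The arrays labelled replicative T0 and 624 h to 2112 h stood apart from all others on component 1. Arrays left on different scales by the authors' normalization are argued against as the whole cause. The SD over features was 1.69 to 1.73 in the arrays above 0, against 1.64 to 1.67 in the others. They had 19 to 57 values below 2, against 4 to 20. Yet quantile normalization, which makes the spreads equal, gave 30550 features at 144 h against T0, where the values as deposited gave 30739. All arrays already had a lower quartile of 4.4 or 4.5 and an upper quartile of 6.8, so this step could change little. It bears on scale alone. Sets of arrays processed apart to the same quantiles were not tested. Titles and value columns permuted between the courses, in pairs of arrays, may account for it and would change what every replicative value means: 12 arrays lay above 0, as many as carry a RAF label, but this was seen first and does not decide, and no array was reassigned. No label names a processing batch, and the test of one does not decide. The share called among the dimmest 25% of features was 0.808 of that among the brightest 25% at 144 h against T0 (95% interval 0.792 to 0.824, for counting error over features only). Between the T0 groups this ratio was 0.746, and the bound was 0.8. In 4 comparisons that do not cross 0 the ratio was 0.145 to 0.227. Those 4 passed only 2.8% to 24.8% of all features, against 58.7% at 144 h and 58.9% between the T0 groups. The ratio can depend on how many features pass, so the comparison is not like for like. Permuted titles, a batch and a difference between cell stocks, which was not tested, cannot be told apart here.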

How the results depend on the processing

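Undoing the rounding and leaving out the arrays labelled replicative 144 h, 264 h and 432 h were chosen after the data were seen, and the other alternatives before. For lists and named genes, the alternatives were run in the 3 main comparisons only. Outside these, lists were tested only with the estimated correlation beside the preset, and single genes under no alternative. In the main comparisons no list or named gene changed direction under any alternative where it passed in that run or with the values as deposited. Changes of sign that passed in neither were not counted. Of the 5185 checks of named genes over the alternatives, 4947 kept their side of the threshold, 213 lost it and 25 gained it, and of the 1176 checks of lists 1141 kept it, 22 lost it and 13 gained it. The estimated correlation accounted for 18 of the lost list calls, in the 3 main comparisons. Median centring moved nothing, since all medians are equal, and says nothing about stability.

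A minimum of 2-fold, which keeps fewer features by construction, gave for RAF against T0 933 at 12 h, 126 at 24 h, 227 at 48 h, 291 at 72 h and 619 at 96 h. For replicative labels against T0 it gave 3363 at 144 h, 3323 at 264 h, 3459 at 432 h, 349 at 624 h, 1540 at 792 h, 1348 at 1008 h, 825 at 1368 h and 42 at 2112 h. It gave 3788 for 2112 h against 144 h, 911 for the difference of effects, 3726 for the T0 groups, 2 reversed early RAF changes, 2363 reversed early replicative changes and 1 shared endpoint feature. An adjusted p under 0.01 gave 6506, 761, 1453, 1928 and 4326 features at the RAF labels in order of time, and 4178 at replicative 624 h, 5844 at 1368 h and 532 at 2112 h. It gave 4623 for the difference of effects, 4571 at any RAF time, 39 reversed early RAF changes and 71 shared endpoint features.

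With only features that have 1 gene symbol, fewer were tested: 13526 passed at replicative 144 h, 13282 at 264 h, 13488 at 432 h, 13777 for 2112 h against 144 h, 13591 between the T0 groups, 17149 at any replicative time and 10758 as reversed early replicative changes. One model of all arrays gave 4829 features at RAF 24 h and 384 reversed early RAF changes; the cause was not tested. With the rounding undone at random, reversed early RAF changes numbered 163 and shared endpoint features 150; the cause was not tested. Without the arrays labelled replicative 144 h, 264 h and 432 h, 17766 features changed at any replicative time. Fewer labels were then compared, and those left out had the largest counts against T0, with 30739, 29776 and 30351 features. They are also the labels that lie across 0 on component 1 from T0.

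With 1 array left out, an arm of 1 array is assumed to vary like the other groups. The counts then ranged from 7663 to 7882 at RAF 12 h, 1195 to 1378 at 24 h, 2236 to 3313 at 48 h, 1603 to 2565 at 72 h and 4989 to 6043 at 96 h. At the replicative labels they ranged from 4035 to 5246 at 624 h and from 377 to 523 at 2112 h. Reversed early RAF changes ranged from 118 to 190 and shared endpoint features from 82 to 178. Every one of these ranges lies below the count from all arrays. The replicate numbers did not pair the arrays as a rule. Deviations of same-numbered arrays correlated at -0.062 to 0.36 over 15 pairs of RAF labels (median 0.02, 3 above 0.1). Over 36 pairs of replicative labels they correlated at -0.28 to 0.31 (median 0.026, 9 above 0.1). Some labels thus shared deviations, and their arrays may not be independent. The replicate number as a block gave 7766 features at RAF 96 h, 1407 at replicative 2112 h and 7291 for the difference of effects. Signal over background is not known for these values, so that no limit for dim features can be given.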

Other observations

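Small nucleolar RNAs of one family set the arrays labelled RAF T0 apart. The median level of the 14 SNORD115 features was 5.2 in these arrays and 2.42, 3.25, 2.75, 2.57 and 2.40 in those labelled RAF 12 h to 96 h. In the replicative arrays it was 2.45 at T0, 3.70 at 264 h and 3.45 at 432 h. Between RAF T0 and RAF 96 h all 14 fell, with a median of -2.58, and 17 of the 18 SNORD116 features, from the same imprinted cluster, fell with a median of -1.13. In the arrays labelled RAF 96 h only 15 and 12 values lay below 2. The SNORD115 level of 2.40 was thus near the low end, and the size of its fall may be understated. The copies of SNORD115 are nearly identical in sequence, so that their features cannot be read as separate measurements, and they were chosen after their values were seen. The SNORD116 level was 6.78 at RAF T0 and 5.28 to 6.10 at the later RAF labels, and at the replicative labels 4.5 at T0, 5.78, 6.43 and 6.5 at 144 h to 432 h and 4.57 at 2112 h, so that RAF T0 hardly stands apart from 432 h for this family. SNORD114, from another imprinted cluster, differed along component 1, with a median level of 6.08 at RAF T0 and 6.10 at replicative 144 h against 5.2 at replicative T0 and 5.25 at 2112 h.

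The test of this pattern was also chosen after these levels had been seen. A rise of all small nucleolar RNA in the arrays labelled RAF T0 is argued against as the whole cause, since the 133 other SNORD features had a median of -0.20 between RAF T0 and RAF 96 h (quartiles -0.75 and 0.10), where SNORD115 had -2.58. Of these 133, 55 fell and 12 rose, so that a smaller fall among other small nucleolar RNAs goes along with it. A change in the cluster itself may remain, and no biological explanation was tested.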
